A study of Homo sapiens with 6 samples.

How the data were processed

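The data are gene counts from 6 RNA-seq libraries of HuCCT1 cells. Per the labels' protocols, cells were grown in serum-supplemented medium and transduced with lentivirus for RNA interference, and libraries were made with an NEBNext Ultra kit and sequenced on an Illumina HiSeq instrument. The values are whole-number counts per gene, not normalized, in a single table deposited by the authors. Per the submitters' processing notes, CASAVA, HISAT2 (version 2.1.0), featureCounts and DESeq2 were used with the genome build GRCh38. Their roles, the gene annotation, the strand setting of the counting and the treatment of reads that match several genes are not given in the sources used here. Reads from overlapping and antisense genes, and from genes with near-identical copies such as ribosomal proteins, GAPDH and histones, can therefore not be told apart in these counts.

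Groups follow the sample titles and treatment labels: 3 libraries labelled Si-Ctrl and 3 labelled Si-CREB3L1. The labels leave 2 points open. The submitters' short codes for the libraries labelled Si-CREB3L1 contain the letters NC, while those labelled Si-Ctrl carry a number code; table columns were matched to samples by these codes, and what the letters stand for is not given in the sources used here. The extraction protocol names bone marrow derived macrophages, while all other labels name HuCCT1 cells. Nothing in the labels says that libraries of a group came from separate cultures, so p-values measure only the spread between these libraries, which may be technical. Within each group every pair of libraries differed by more than sampling noise (chi-square per degree of freedom 5.12 to 37.0), and all 6 were kept as separate replicates.

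Differences were tested with edgeR 4.0.16 (quasi-likelihood F test) in R 4.3.3, after filterByExpr and TMM normalization, with Benjamini-Hochberg adjustment and a threshold of 0.05. All 6 libraries entered the fit, with the group as the only term. Log2 CPM values used a prior count of 2. Every count in the table belonged to a row with a gene name. CREB3L1 was also tested with an exact two-sided permutation test, for which 3 against 3 libraries give a smallest p of 0.1. Gene lists were tested with camera (limma 3.58.1) at a preset correlation of 0.01, again with an estimated correlation, and with fry. Camera compares a list with all other genes; fry asks whether the members of a list move, on balance, in 1 direction. List p-values were adjusted over the 28 lists with at least 5 tested members, and 3 of the 31 lists had fewer and are only described. Fry passed 6 lists: biliary and epithelial markers (adjusted p = 0.00333), oxidative phosphorylation, ribosomal proteins and fibroblast markers (0.0111 each), and YAP targets and fatty acid synthesis (0.0444 each). Sterol synthesis (0.171), hypoxia and glycolysis (0.0606) and G2/M genes (0.0906) did not pass fry, although camera passed them at the preset correlation.

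GC content and length were taken from GENCODE release 29 (GRCh38), for the longest protein-coding transcript of a gene or else its longest transcript; 99.2% of tested genes had a value. Coordinates come from the same annotation. The trends of log2 CPM on GC content and on log2 length were fitted in each library with natural splines of 5 degrees of freedom, on genes with a mean log2 CPM above 1, and entered as an offset. This alternative was chosen after seeing the data. CREB3L1 was also compared with tested genes within 2 percentage points of GC content, 0.5 in log2 length and 1 in log2 CPM.

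The genes named were chosen by a rule fixed before the data were examined, as were the gene lists and all alternatives not described as added. The rule names CREB3L1 and the 10 largest rises and 10 largest falls among genes that passed the test, had at least 10 CPM on average, had groups that did not overlap, and had a symbol other than a clone or locus identifier. XIST and Y-linked genes are left out of it. It also names up to 4 members per list with the smallest adjusted p, or the 2 most abundant where none passed, and the 3 most abundant genes. Some list members that the rule names are not reported here.

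The fit was tested on simulated counts for 14642 genes with 200 changed genes. It recovered 26.3%, 68.3% and 95.0% of genes changed 1.5-fold, 2-fold and 4-fold, and called 8 unchanged genes. With the GC and length trends of the real libraries added to the simulation, the fit without trend removal called 2520 genes, of which 2388 were unchanged. With trend removal it called 120, of which 6 were unchanged, and recovered 23.8%, 61.7% and 96.7%. The added trends had the same form that the removal fits, and changed genes were drawn without regard to GC content or length. The simulation therefore cannot show whether removal takes away true differences that follow GC content, or handles trends of another form. In the simulated list test the shifted list was called and 0 of the others. The genes of that test were drawn independently of each other and without the trends. In the real libraries the estimated correlation was 0.56 for sterol synthesis and 0.50 for ribosomal proteins. The simulated list test therefore cannot show how camera at the preset correlation behaves for lists whose members move together.

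The alternatives set before the data were examined were DESeq2 size factors, upper-quartile factors and library totals for scaling; no filter on low counts, or at least 1 CPM in 3 libraries; the replicate number as a block; each library left out in turn; the DESeq2 Wald test (version 1.42.0) and limma-voom; protein-coding genes only; an adjusted p under 0.01; and a fold change of at least 2. Alternatives added after seeing the data were removal of the GC trend, the length trend or both, both with the replicate block or with limma-voom, and thinning of every library to the smallest total. No scaling moved the median of all genes by more than 0.064 on the log2 scale.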

Results

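RNA sequencing measured gene expression in HuCCT1, an established human cell line from an intrahepatic cholangiocarcinoma, a cancer of the bile duct epithelium. Lentiviral RNA interference was directed at CREB3L1, a membrane-bound transcription factor of the endoplasmic reticulum (ER) that is cleaved in the Golgi before its amino-terminal part enters the nucleus. The 6 libraries were labelled Si-Ctrl (3 libraries) and Si-CREB3L1 (3 libraries), and the single comparison of the design is between these 2 groups. Total counts were 20630448, 15426258 and 21665813 in the libraries labelled Si-Ctrl and 18237084, 20928206 and 18858686 in those labelled Si-CREB3L1. Mean depth did not differ detectably between the groups, with an exact two-sided permutation p of 0.9 (n = 3 each). Of 60623 genes in the table, 14899 had enough counts to be tested. Fold changes are given throughout as libraries labelled Si-CREB3L1 over libraries labelled Si-Ctrl.

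The targeted gene was examined first, as a check of the labels. CREB3L1 RNA was higher, not lower, in the libraries labelled Si-CREB3L1: 3.18 ± 0.57 CPM (counts scaled to library size; SD, n = 3) against 1.76 ± 0.49 CPM in those labelled Si-Ctrl. The gene (ENSG00000157613) lies on chromosome 11 at 46277661 to 46321422, plus strand, of GRCh38. Its raw counts were 41, 32 and 27 in the libraries labelled Si-Ctrl and 60, 75 and 48 in those labelled Si-CREB3L1, so that every library of the second group lay above every library of the first. The difference was 1.82-fold (log2 0.86, SE 0.28, 95% interval 0.23 to 1.49). It did not pass the threshold in edgeR's quasi-likelihood test (adjusted p = 0.0582), and an exact two-sided permutation test gave p = 0.1, the smallest value that 3 against 3 libraries allow. Over 21 alternative settings the adjusted p ranged from 0.0164 to 0.365 and was under the threshold in 4, with CREB3L1 higher in the libraries labelled Si-CREB3L1 in each. With each library's trend on GC content and transcript length removed, the log2 difference was 0.49 (SE 0.25, 95% interval -0.088 to 1.06). The groups then overlapped, with Si-CREB3L1 replicate 3 (log2 CPM 1.28) below Si-Ctrl replicate 1 (1.33). The exact two-sided permutation test then gave p = 0.2. Because the targeted gene goes against the labels, no direction given below can be read as an effect of lowered CREB3L1 RNA.

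**Figure D1:**
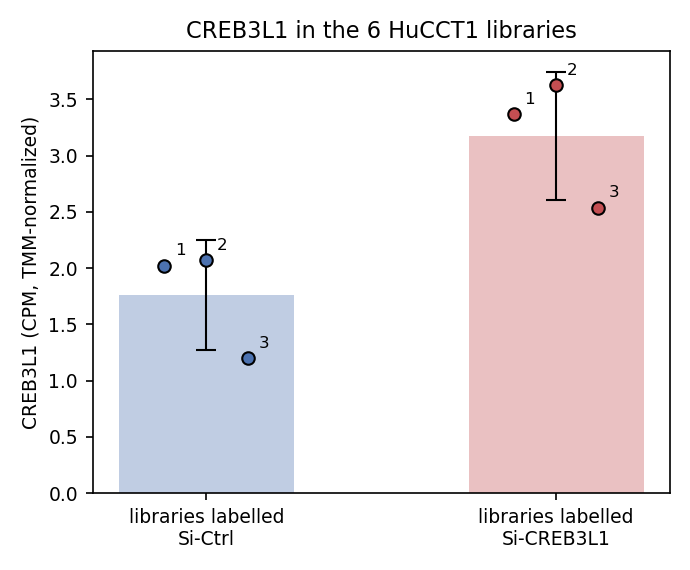
CREB3L1 in CPM (vertical axis) in each of the 6 libraries; points are libraries with their replicate number, bars are group means and error bars are SD (n = 3). The libraries labelled Si-CREB3L1 lie between 2.54 and 3.63 CPM, all above those labelled Si-Ctrl, which lie between 1.20 and 2.07 CPM.

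In the libraries labelled Si-CREB3L1, 1094 genes were higher and 1896 lower (2990 of 14899, 20.1% of those tested, edgeR quasi-likelihood test with Benjamini-Hochberg adjustment). The largest differences were falls: 520 genes were lower by at least 2-fold and 19 were higher by as much. With upper-quartile scaling the split of higher against lower calls was 1629 to 1702, so that 51.1% of calls were lower, against 63.4% with the scaling used here. The groups did not overlap in 40.7% of tested genes, where chance gives 10%. No gene was called by edgeR when Si-Ctrl replicate 1 was left out (3749 genes at an unadjusted p under 0.05) or when Si-CREB3L1 replicate 2 was left out (3586 genes), and 1352 were called without Si-CREB3L1 replicate 3.

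Of the 10 largest falls, ASPM, CENPE and CENPF are members of the G2/M and mitosis list. ASPM, a spindle pole protein (chromosome 1, 197084128 to 197146694), fell from 114.8 ± 33.0 to 33.1 ± 5.2 CPM (SD, n = 3 each; log2 -1.80, SE 0.22, edgeR adjusted p = 0.0152). The kinetochore proteins CENPE and CENPF had log2 fold changes of -1.82 (SE 0.37) and -1.67 (SE 0.25). The mitotic kinesins KIF20B and KIF18A were at -1.76 (SE 0.30) and -1.62 (SE 0.27). BRCA2, which acts in repair of DNA breaks by homologous recombination, was at -1.91 (SE 0.28), and RIF1, a regulator of replication timing, at -1.62 (SE 0.25). The nucleolar protein ESF1 (-1.70), the early endosome tether EEA1 (-1.65) and BDP1, a subunit of the RNA polymerase III initiation factor (-1.62), completed the 10 largest falls. Adjusted p over these 10 genes ran from 0.0152 to 0.0172.

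The rises were smaller. FAM83A (chromosome 8, 123178960 to 123210079) rose from 14.3 ± 1.79 to 27.6 ± 4.81 CPM (SD, n = 3 each; log2 0.94, SE 0.17, edgeR adjusted p = 0.0152). The adhesion receptor ADGRG3 was at log2 0.96 (SE 0.21). MVK and MVD, enzymes of the mevalonate pathway, were at 0.87 (SE 0.20) and 0.82 (SE 0.22). CDKN1A, an inhibitor of cyclin-dependent kinases, was at 0.87 (SE 0.23). The other 5 of the 10 largest rises were DES (desmin, 0.87), the netrin receptor UNC5B (0.85), the glycosyltransferase A4GALT (0.85), the tetraspanin CD82 (0.82) and PALM (0.81). Adjusted p over the 10 ran from 0.0152 to 0.0345.

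Higher and lower genes differed in base composition and length. Median transcript GC content was 58.1% for the higher genes, 39.5% for the lower genes and 48.4% for all tested genes, and median length was 2110, 5258 and 3006 bases. Of 1890 lower genes with a GC value, 1789 were under 45% GC, and of 1094 higher genes 988 were at 50% or more. Across genes, which are not independent replicates, the log2 fold change had a Spearman correlation of 0.71 with GC content and -0.31 with length, and both together accounted for 52.3% of its variance. The 10 named falls had 34.2% to 40.8% GC and the 10 named rises 54.9% to 67.9%. The mean GC content of the transcripts counted, weighted by reads, was 48.2 ± 0.57% in the libraries labelled Si-Ctrl and 49.5 ± 0.23% in those labelled Si-CREB3L1 (SD, n = 3 each, exact two-sided permutation p = 0.1, the smallest possible). Once each library's trend on GC content and length was removed, edgeR called 0 genes (2600 at an unadjusted p under 0.05, smallest adjusted p 0.0781), and limma-voom also called 0 (2570 unadjusted). The 10 named falls then had log2 fold changes of -1.04 to -0.75 (adjusted p 0.0781 to 0.234) and the 10 named rises 0.39 to 0.77 (adjusted p 0.0895 to 0.467). The first principal component with the trends removed (49.5% of variance) crossed the labelled groups, placing Si-CREB3L1 replicate 1 with Si-Ctrl replicates 1 and 2, and Si-Ctrl replicate 3 with the other Si-CREB3L1 libraries. Without trend removal the first component (50.3%) separated the groups, at -45.7, -14.7 and -25.8 for Si-Ctrl against 22.5, 40.4 and 23.3 for Si-CREB3L1. The second component without removal (31.7%) crossed the groups in the same way by sign.

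**Figure D2:**
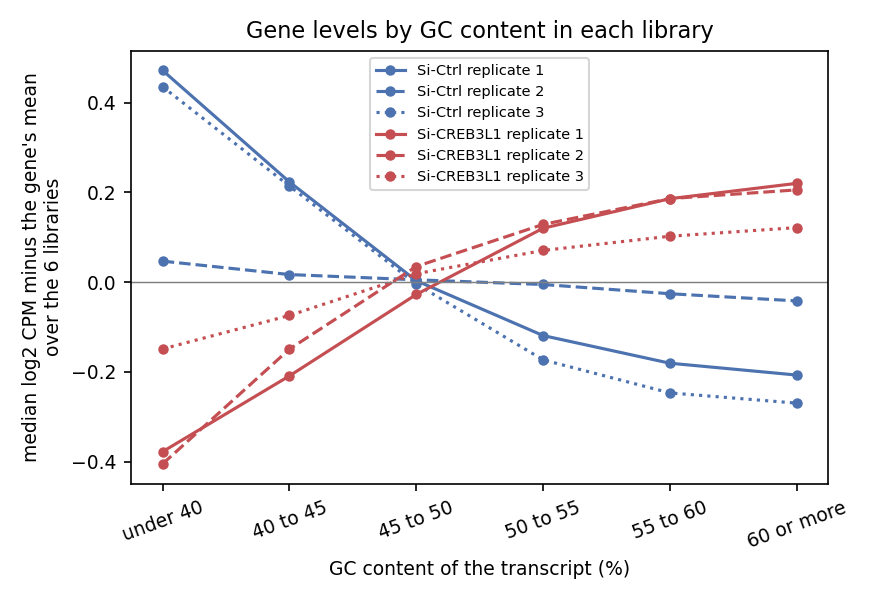
Median deviation of genes from their own mean over the 6 libraries (vertical axis, log2 CPM) by transcript GC content (horizontal axis, percent), with 1 line per library. Genes under 40% GC deviate by 0.47, 0.047 and 0.44 in Si-Ctrl replicates 1, 2 and 3 and by -0.38, -0.40 and -0.15 in Si-CREB3L1 replicates 1, 2 and 3.

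Of 28 gene lists fixed before the data were examined and tested with limma's camera, 6 passed at the preset correlation of 0.01, and none passed with an estimated correlation (smallest adjusted p = 0.579 with an estimated correlation). With the GC and length trends removed 8 lists passed at the preset correlation, these 6 together with fatty acid synthesis and Golgi transport, and again none with an estimated correlation. Ribosomal proteins and respiratory chain subunits were the lists with the smallest p. Among cytosolic ribosomal proteins, 63 of 78 rose and 0 fell (67 and 0 adjusted over the list alone), with a median log2 fold change of 0.41 (camera adjusted p = 1.31e-21; adjusted p = 0.579 with an estimated correlation). RPL13A was at 0.61 (SE 0.09) and RPS14 at 0.52 (SE 0.08). Many ribosomal protein genes have processed pseudogenes that can take up part of their reads, so that single values are uncertain. Among nuclear-encoded subunits of oxidative phosphorylation, 26 of 60 rose and 0 fell (36 and 1 adjusted over the list alone), with a median of 0.33 (camera adjusted p = 3.47e-09; adjusted p = 0.579 with an estimated correlation). UQCRC1 was at 0.50 (SE 0.09) and COX4I1 at 0.47 (SE 0.09). With the GC and length trends removed, the medians were 0.18 and 0.16, and the list means of the groups did not overlap for either list, with or without the trends.

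Genes of sterol synthesis and of hypoxia and glycolysis were higher in the libraries labelled Si-CREB3L1, although neither list passed fry (adjusted p = 0.171 and 0.0606). In the sterol list 11 of 25 rose and 0 fell (14 and 0 adjusted over the list alone), with a median of 0.50 (camera adjusted p = 9.96e-05; adjusted p = 0.685 with an estimated correlation). They included LSS (0.63, SE 0.12), which closes the sterol ring, and FDPS (0.50, SE 0.11). In the hypoxia and glycolysis list 11 of 36 rose and 0 fell (18 and 0 adjusted over the list alone), with a median of 0.39 (camera adjusted p = 3.69e-05; adjusted p = 0.579 with an estimated correlation). The members that passed with the smallest p were glycolytic enzymes: GAPDH (0.51, SE 0.08), TPI1 (0.52, SE 0.09), PGK1 (0.45, SE 0.08) and PKM (0.42, SE 0.09). For both lists the group means overlapped: Si-Ctrl replicate 3 lay at 0.085 and 0.012 (log2, relative to the mean of the 6 libraries), above Si-CREB3L1 replicate 1 at -0.072 and -0.047. With the trends removed the medians were 0.33 and 0.16, and the group means again overlapped. Si-Ctrl replicate 3 then lay at 0.13 and 0.10, above Si-CREB3L1 replicate 1 at -0.085 and -0.094. In the fatty acid and triglyceride list 5 of 23 rose and 3 fell, the same counts as adjusted over the list alone (median 0.33, camera adjusted p = 0.188, from 0.00359 to 0.283 over 17 alternatives, under the threshold in 4). It passed with the trends removed (median 0.14, adjusted p = 0.00452; adjusted p = 0.289 with an estimated correlation), and its group means did not overlap with or without them. FASN, fatty acid synthase, was at 0.54 (SE 0.10) and the desaturase SCD at 0.53 (SE 0.14), while GPAM was at -0.68 (SE 0.14) and ACSL3 at -0.60 (SE 0.15).

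G2/M and mitosis genes were lower: 18 of 40 fell and 0 rose (18 and 0 adjusted over the list alone), with a median of -0.25 (camera adjusted p = 3.54e-06; adjusted p = 0.676 with an estimated correlation). The list did not pass fry (adjusted p = 0.0906). Besides ASPM and CENPF, ANLN, a scaffold of cytokinesis, was at -1.19 (SE 0.17) and topoisomerase TOP2A at -1.33 (SE 0.20). All 18 were among the 31 members under 50% GC, whose median was -0.55. The 9 members at 50% GC or more (AURKB, BIRC5, CDC20, CDCA3, CDCA8, FOXM1, KIF2C, PLK1 and UBE2C, chosen by GC content after the data were seen) had a median of 0.16, and 0 of them passed. With the trends removed the list median was -0.20, and Si-CREB3L1 replicate 1 (0.12) lay above Si-Ctrl replicate 3 (-0.068). Among MCM and G1/S genes 7 of 36 rose and 4 fell, the same counts as adjusted over the list alone (median 0.15, camera adjusted p = 0.225), with RFC3 at -0.70 (SE 0.13), POLA1 at -0.75 (SE 0.15) and MCM5 at 0.50 (SE 0.12). Among YAP and TEAD targets 3 of 22 fell and 0 rose, the same counts as adjusted over the list alone: TGFB2 (-0.64, SE 0.12), ASAP1 (-0.49, SE 0.11) and DLC1 (-0.45, SE 0.13). Their median was -0.29 (camera adjusted p = 0.0478, from 0.000118 to 0.311 over 17 alternatives, under the threshold in 9; adjusted p = 0.579 with an estimated correlation). The call on this list was lost without Si-Ctrl replicate 2, Si-CREB3L1 replicate 2 or Si-CREB3L1 replicate 3 (adjusted p = 0.283, 0.0566 and 0.158). Its group means overlapped, with Si-Ctrl replicate 3 at -0.0034 and Si-CREB3L1 replicate 1 at -0.00093.

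**Figure D3:**
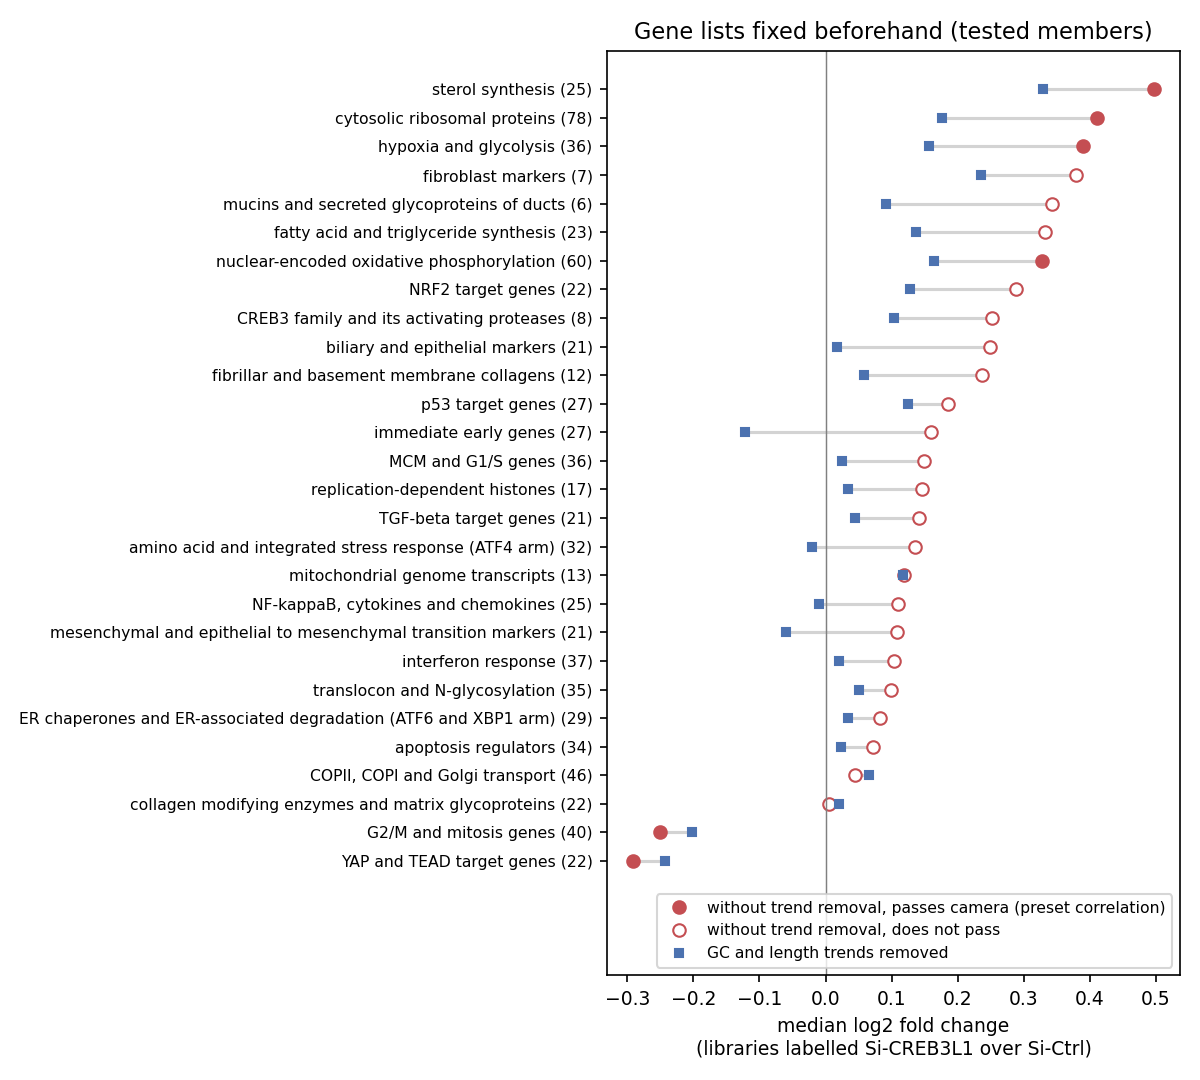
Median log2 fold change (horizontal axis) of each of the 28 tested gene lists, with the number of tested members in brackets; circles are values without trend removal, filled where the list passed camera at the preset correlation, and squares are values with each library's GC and length trends removed. Sterol synthesis has the highest median, 0.50 before and 0.33 after removal, and YAP and TEAD targets the lowest, -0.29 before and -0.24 after.

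**Figure D4:**
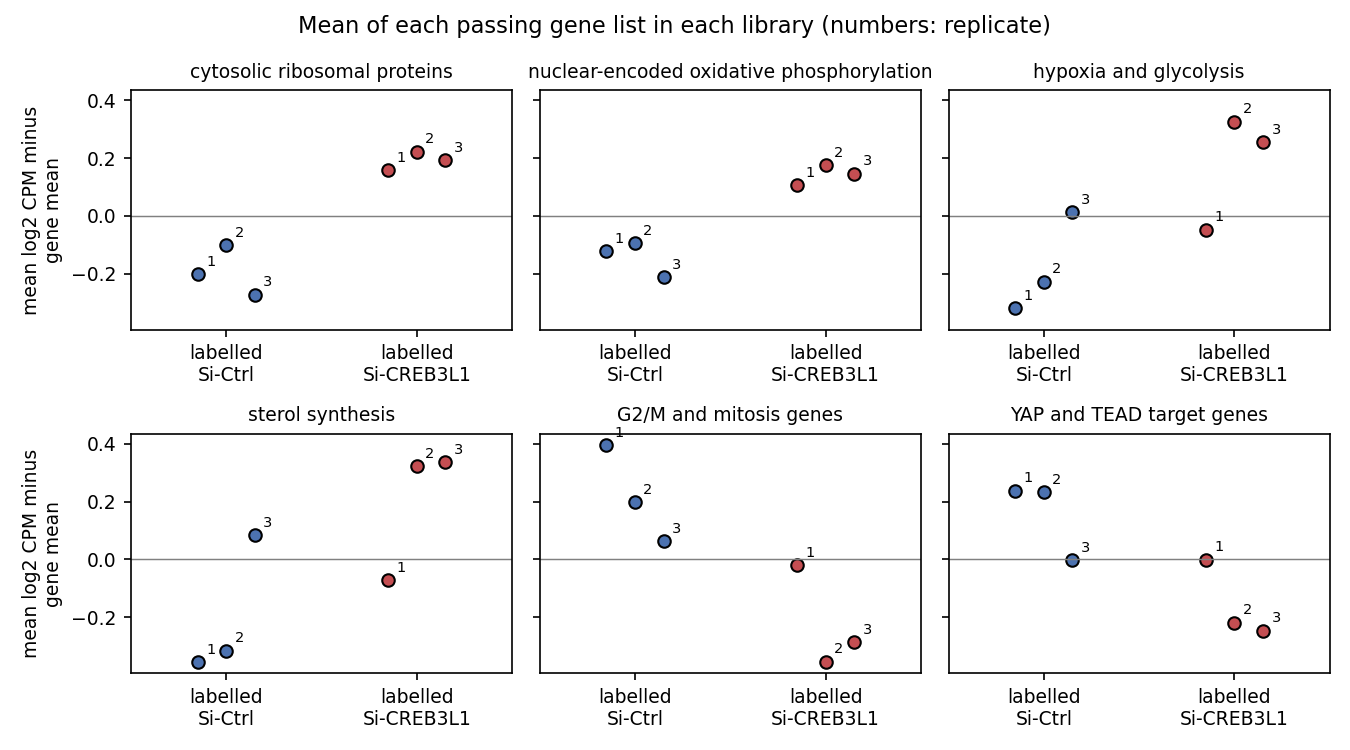
Mean log2 CPM of the members of the 6 passing lists in each library (vertical axis), relative to each gene's mean over the 6 libraries; points are libraries with their replicate number. The groups do not overlap for ribosomal proteins, oxidative phosphorylation and G2/M genes, while Si-Ctrl replicate 3 (0.085) lies above Si-CREB3L1 replicate 1 (-0.072) for sterol synthesis. For YAP and TEAD targets, which are lower by median, Si-Ctrl replicate 3 (-0.0034) lies below Si-CREB3L1 replicate 1 (-0.00093).

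The lists closest to the known roles of the CREB3 family, secretion and collagen production, held members that went both ways. Of 8 CREB3 family members and their activating proteases, CREB3 rose (0.46, SE 0.12) and the protease MBTPS2 fell (-0.64, SE 0.13), with 1 and 1 adjusted over the list alone; with the trends removed MBTPS2 was at 0.062. In the list of COPII, COPI and Golgi transport 6 of 46 rose and 7 fell (11 and 8 adjusted over the list alone), among them GOLGB1 (-1.41, SE 0.19), LMAN1 (-0.86, SE 0.19), COPB1 (-0.82, SE 0.18) and TMED9 (0.45, SE 0.10). In the translocon and N-glycosylation list 6 of 35 rose and 5 fell (9 and 9 adjusted over the list alone), with SEC62 at -1.12 (SE 0.18), SEC63 at -0.82 (SE 0.15), SRP72 at -0.67 (SE 0.13) and DAD1 at 0.51 (SE 0.11). Of 29 ER chaperone and ER-associated degradation genes 3 rose and 6 fell, the same counts as adjusted over the list alone; SEL1L was at -0.80 (SE 0.13), DNAJC10 at -0.91 (SE 0.16), DNAJC3 at -0.63 (SE 0.14) and SDF2L1 at 0.75 (SE 0.14). With the trends removed SEL1L, DNAJC10, DNAJC3 and SDF2L1 were at -0.15, -0.035, -0.064 and 0.26, and GOLGB1 and SEC62 at -0.87 and -0.37. None of these 4 lists passed camera (adjusted p 0.545, 0.803, 0.565 and 0.765, in this order). The transport list passed with the trends removed (median 0.065, adjusted p = 0.024, from 0.0178 to 0.925 over 17 alternatives; adjusted p = 0.353 with an estimated correlation). The last 3 had medians of 0.045, 0.099 and 0.083 and a camera direction upwards, but negative means of -0.055, -0.0015 and -0.015.

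Among fibrillar and basement membrane collagens 3 of 12 rose and 1 fell, the same counts as adjusted over the list alone (median 0.24, camera adjusted p = 0.188). COL1A1 was at 0.53 (SE 0.12), COL5A1 at 0.37 (SE 0.09) and COL4A2 at 0.36 (SE 0.11), and COL12A1 at -0.42 (SE 0.12). The median GC content of the list was 60.7%, and with the trends removed its median was 0.059. Of 22 collagen modifying enzymes and matrix glycoproteins 2 rose and 1 fell, also adjusted over the list alone: PLOD1 (0.43, SE 0.10), P4HA2 (0.47, SE 0.13) and PLOD2 (-0.74, SE 0.17). Their median of 0.0050 (camera adjusted p = 0.545) changed sign with DESeq2 size factors (-0.012) and with library totals alone (-0.025). TGF-beta targets were divided, with 4 of 21 higher and 4 lower, also adjusted over the list alone (median 0.14, camera adjusted p = 0.565): TGFB1 was at 0.61 (SE 0.12), LTBP3 at 0.56 (SE 0.14) and SKIL at -0.94 (SE 0.19).

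Biliary and epithelial markers held 5 higher and 2 lower genes of 21 (6 and 3 adjusted over the list alone; median 0.25, camera adjusted p = 0.188). Fry passed this list (adjusted p = 0.00333). The transcription factor ELF3 was at 0.48 (SE 0.11) and the claudin CLDN7 at 0.75 (SE 0.18), while the junction protein TJP1 was at -0.69 (SE 0.15) and ONECUT2 at -0.84 (SE 0.21). Mesenchymal markers held 5 higher and 5 lower genes of 21 (6 and 5 adjusted over the list alone). ZEB1 (-1.32, SE 0.23) and ZEB2 (-1.003, SE 0.17), repressors of epithelial genes, and the integrin ITGAV (-0.99, SE 0.18) fell, and S100A4 (0.56, SE 0.11) rose. The median of that list was 0.11, its mean -0.061 and its camera direction downwards (adjusted p = 0.949). The biliary list had a median GC content of 56.0% and a median of 0.017 with the trends removed, whereas ZEB1, ZEB2 and ITGAV have 38.5%, 39.1% and 38.2% GC. With the trends removed these 3 genes were at -0.63, -0.30 and -0.29 (edgeR adjusted p = 0.0955, 0.367 and 0.144). Of 6 tested mucin and duct secretion genes 1 rose, also adjusted over the list alone: the protease inhibitor SLPI (0.52, SE 0.11; list camera adjusted p = 0.353).

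Stress, survival and inflammatory lists did not pass camera with all 6 libraries and the settings used here, but 3 passed in other settings. The p53 targets passed without Si-Ctrl replicate 3 (median 0.31, adjusted p = 0.0282, from 0.0282 to 0.426 over 17 alternatives, under the threshold in 2). NRF2 targets passed without Si-CREB3L1 replicate 1 (median 0.35, adjusted p = 0.0287, from 0.0287 to 0.384 over 17, under it in 1). The libraries left out for these p53 and NRF2 calls were those that crossed the groups on the first component with the trends removed. A link of these calls to the label is therefore not shown. Immediate early genes passed with no low-count filter (median 0.17, adjusted p = 0.0292, from 0.0292 to 0.880 over 17, under it in 1). These 3 calls used the preset correlation only. With all 6 libraries and an estimated correlation, camera gave an adjusted p of 0.739 for each of the 3 lists. In the ATF4 arm of the stress response 4 of 32 rose and 2 fell (7 and 3 adjusted over the list alone; median 0.14, camera adjusted p = 0.237), with the cystine transporter SLC7A11 at -1.26 (SE 0.18) and SHMT2 at 0.46 (SE 0.11). Among p53 targets 7 of 27 rose and 2 fell, also adjusted over the list alone (median 0.19, adjusted p = 0.225): FDXR was at 0.63 (SE 0.15) and BAX at 0.50 (SE 0.13), and MDM2 at -0.67 (SE 0.14) and RRM2B at -0.99 (SE 0.23). NRF2 targets held 4 higher and 3 lower genes of 22 (7 and 4 adjusted over the list alone; median 0.29, adjusted p = 0.225), with FTL at 0.53 (SE 0.10) and TKT at 0.46 (SE 0.09). Apoptosis regulators held 4 higher and 3 lower genes of 34, also adjusted over the list alone (median 0.071, adjusted p = 0.664), with CASP9 at 0.61 (SE 0.13), XIAP at -0.71 (SE 0.13) and BIRC2 at -0.97 (SE 0.21). In the interferon list 6 of 37 rose and 7 fell (10 and 10 adjusted over the list alone). SAMD9 (-1.56, SE 0.28), DDX58 (-0.83, SE 0.15) and IFIT2 (-0.81, SE 0.15) fell and BST2 (0.54, SE 0.10) rose. The median of the interferon list was 0.10, its mean -0.068, its camera direction upwards (adjusted p = 0.969) and its fry direction downwards. Of 25 NF-kappaB, cytokine and chemokine genes 2 rose and 1 fell (0 and 0 adjusted over the list alone; median 0.11, adjusted p = 0.516): IER3 (0.64, SE 0.15), TNFAIP2 (0.37, SE 0.11) and BIRC3 (-1.11, SE 0.33). Of 27 immediate early genes 3 rose and 0 fell (2 and 0 adjusted over the list alone; median 0.16, adjusted p = 0.188): ETV4 (0.55, SE 0.12), JUNB (0.75, SE 0.19) and FOS (0.57, SE 0.17).

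The 3 most abundant transcripts were mitochondrial: MT-CO1 (12767 CPM on average), MT-RNR2 (12742 CPM) and MT-ND4 (11192 CPM). MT-CO1 rose (log2 0.27, SE 0.07, edgeR adjusted p = 0.0368) and was the only member of the 13 mitochondrial genome transcripts to pass, with 0 adjusted over the list alone (median 0.12, camera adjusted p = 0.237). The mitochondrial genome took 6.73 ± 0.44% of counts in the libraries labelled Si-Ctrl and 7.48 ± 0.09% in those labelled Si-CREB3L1 (SD, n = 3 each, exact two-sided permutation p = 0.1, the smallest possible). None of 17 replication-dependent histone genes passed, and 0 adjusted over the list alone (median 0.15, camera adjusted p = 0.265); the most abundant were H2BC12 (52.5 CPM) and H2AC6 (33.2 CPM).

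Most markers of other cell types had too few counts to be tested, but some were abundant. Of 20 macrophage and leukocyte markers 3 were tested, and 8 had a median count of 0. The highest was LAPTM5 at 12.7 CPM (log2 0.66, SE 0.18), the only tested marker that rose, also adjusted over the list alone. Of 20 hepatocyte markers only CPS1, a urea cycle enzyme, was tested; it stood at 2551 CPM (log2 -0.28, SE 0.10, adjusted p = 0.0778; 1 lower adjusted over the list alone). Of 12 endothelial markers 4 were tested and 1 rose, also adjusted over the list alone: EGFL7 (0.53, SE 0.14). The highest was CDH5 at 34.1 CPM. Of 15 fibroblast markers 7 were tested, and FBLN1 was the highest at 560 CPM. Of these 7, 3 rose and 1 fell (4 and 1 adjusted over the list alone, median 0.38, camera adjusted p = 0.237). FBLN1 was at 0.38 (SE 0.11), MMP2 at 0.55 (SE 0.10) and FAP at -0.84 (SE 0.22). The list passed fry (adjusted p = 0.0111), and its group means did not overlap with or without the trends. With the trends removed its median was 0.24 (camera adjusted p = 0.132). COL1A1 also belongs to the collagen list.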

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

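Trend removal and thinning were chosen after seeing the data; the other settings were fixed before. All 116 named genes kept their direction under every setting fixed before, and 2 also kept their side of the threshold. Of 28 list medians, 25 kept their direction under every such setting, and 20 also their side. The 2990 calls (1094 higher, 1896 lower) became 5069 (2333 higher) with the replicate block, 539 (19 and 520) at 2-fold or more and 0 at an adjusted p under 0.01 (edgeR; 5567 at an unadjusted p under 0.05). The DESeq2 Wald test gave 3863 calls (2920 shared) and limma-voom 3027 (2933 shared). Leaving out a library gave 0 to 3699 calls (0 to 1271 higher, 0 to 2428 lower): 0 without Si-Ctrl replicate 1 or Si-CREB3L1 replicate 2, and 1352 (142 and 1210) without Si-CREB3L1 replicate 3. Such fits have fewer samples, and the cause was not tested further. Camera called 0 of 28 lists with an estimated correlation, and 5 to 7 with a library left out. CREB3L1 rests on 27 to 75 counts a library.

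The replicate numbers are shared by title only. Residuals of same-numbered libraries correlated at 0.41, -0.064 and 0.55. Si-Ctrl replicates 1 and 3 correlated best with the library of their own number, but Si-Ctrl replicate 2 with Si-CREB3L1 replicate 1 (0.43). This check therefore leaves open whether the numbers pair the libraries. With the replicate block CREB3L1 was at 0.86 (adjusted p = 0.0164), and 1 passing list, YAP targets, lost its call (adjusted p = 0.0587). The block with both trends removed gave 1171 calls (546 higher, 625 lower).

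CREB3L1 passed the threshold with upper-quartile factors (log2 0.93, adjusted p = 0.0426), no filter (0.87, 0.0366) and the DESeq2 Wald test (0.87, 0.0413); the cause was not tested. With a library left out it ranged from 0.65 to 1.00 (adjusted p 0.0605 to 0.214).

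Removal of both trends left 0 calls (0 higher, 0 lower) with edgeR (2600 unadjusted) and with limma-voom (2570 unadjusted). Removing the GC trend alone left 209 (85 and 124; 161 shared), and the length trend alone 2364. Of 116 named genes 111 had passed, and all 111 lost their call with both trends removed. Some log2 fold changes then lay near 0, such as TGFB2 (-0.040), XIAP (-0.040), SKIL (-0.10) and PLOD2 (-0.12). Others were larger than without removal, such as PGK1 (0.75 against 0.45) and SCD (0.60 against 0.53), so a lost call alone does not assign a gene's difference to the trends. MBTPS2 (0.062), ACSL3 (0.069), H2BC12 (-0.23) and CPS1 (0.011) changed sign, as they did with the block added (0.064, 0.067, -0.23 and 0.017) and in limma-voom (0.068, 0.068, -0.23 and 0.021). With the GC trend alone removed these were MBTPS2 (0.059), COL4A2 (-0.0059), ACSL3 (0.026) and H2BC12 (-0.034), and with length alone H2AC6 (-0.022) and MT-ND4 (-0.068).

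None of the lists whose median changed sign passed camera with the settings of the report, and the cause was not tested; the immediate early list passed with no filter (0.17, adjusted p = 0.0292). With 1 trend removed collagens (0.49, 8.57e-05) and collagen modifying enzymes (0.26, 0.0142) passed for length, and mitochondrial transcripts (0.31, 3.52e-05) for GC. These calls used the preset correlation only. Without trend removal, camera with an estimated correlation gave these lists adjusted p of 0.680, 0.741 and 0.741. With both trends removed the lists that changed sign were the ATF4 arm (-0.021), mesenchymal (-0.061), NF-kappaB (-0.010) and immediate early (-0.12) lists, and with the replicate block added -0.020, -0.061, -0.012 and -0.12. With the GC trend alone removed they were collagens (-0.066), collagen modifying enzymes (-0.061), the ATF4 arm (-0.0039), biliary (-0.042), mesenchymal (-0.082), TGF-beta (-0.039) and immediate early (-0.087) lists. With the length trend alone removed they were mesenchymal (-0.018), mitochondrial (-0.081) and histone (-0.022) lists. Collagen modifying enzymes were at -0.012 with DESeq2 size factors, -0.025 with library totals, -0.022 with no filter and -0.020 with the 1 CPM filter. The interferon list was at -0.26 with no filter, -0.29 with the 1 CPM filter and -0.22 when thinned. With a library left out, collagen modifying enzymes ranged from -0.048 to 0.14 (negative without Si-Ctrl replicate 1, -0.048, or Si-CREB3L1 replicate 2, -0.015). The interferon list ranged from -0.14 to 0.22 and was negative without Si-Ctrl replicate 3 (-0.076), Si-CREB3L1 replicate 1 (-0.12) or Si-CREB3L1 replicate 3 (-0.14). The translocon list ranged from -0.0056, without Si-Ctrl replicate 3, to 0.20.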

Other observations

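Trend removal, its use on CREB3L1 and on G2/M genes, and the components and splits computed with trends removed were chosen after the results were seen. The tests within lists, by thinning, against matched genes, by GC class of the G2/M genes and over splits without trend removal were set before their own results were seen. Of these, thinning and the GC classes were nevertheless chosen after the data had been seen. A further axis of expression crossed the labelled groups. With each library's GC and length trends removed, the first principal component (49.5% of variance) placed Si-Ctrl replicates 1 and 2 and Si-CREB3L1 replicate 1 at -31.6, -27.1 and -16.3, and Si-Ctrl replicate 3 and Si-CREB3L1 replicates 2 and 3 at 18.1, 29.3 and 27.8. Genes with the strongest positive loadings, named after their values were seen, included GDF15, a stress-induced cytokine, the cyclin G family member CCNG2, the hypoxia-responsive genes NDRG1, BNIP3L and SLC2A3, the neuronal enolase ENO2 and the sterol enzyme MSMO1. GDF15 deviated from its mean by -0.87, -0.68 and 0.80 (log2) in Si-Ctrl replicates 1, 2 and 3 and by -0.93, 0.90 and 0.78 in Si-CREB3L1 replicates 1, 2 and 3. At the negative end were CCN2, FJX1 and THBS1, of which the first 2 are in the YAP list, the cyclin CCND1, MYBL2 and ATF5. MYBL2 deviated by 0.76, 0.76 and -0.75 in the Si-Ctrl libraries and by 0.74, -0.74 and -0.77 in the Si-CREB3L1 libraries.

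Fixed lists lay along this axis too. With the trends removed, p53 targets averaged -0.21, -0.16 and 0.15 in Si-Ctrl replicates 1, 2 and 3 and -0.11, 0.17 and 0.17 in Si-CREB3L1 replicates 1, 2 and 3, and NRF2 targets -0.17, -0.078 and 0.011 against -0.095, 0.18 and 0.15. Sterol genes averaged -0.35, -0.30 and 0.13 against -0.085, 0.30 and 0.31, and YAP targets 0.22, 0.23 and -0.0025 against 0.030, -0.22 and -0.25. Hypoxia and glycolysis genes averaged -0.27, -0.22 and 0.10 against -0.094, 0.26 and 0.22. That list includes NDRG1, BNIP3L, SLC2A3 and ENO2, named above for their loadings. Ribosomal proteins did not follow it, at -0.12, -0.064 and -0.14 against 0.086, 0.12 and 0.12. Of the 10 splits of the 6 libraries into 3 and 3, the one along this axis gave 3248 calls with the trends removed, against 0 for the labelled groups and for each of the other 8. This count restates the component, and both describe a structure of the libraries other than the labelled groups. An exchange of Si-Ctrl replicate 3 and Si-CREB3L1 replicate 1, or a batch, was neither tested nor excluded; under an exchange each group mean and fold change in the report would compare other groups. CREB3L1 itself did not follow the axis, at 1.20 CPM in Si-Ctrl replicate 3, the lowest of the 6 libraries, and 3.37 CPM in Si-CREB3L1 replicate 1.

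Without trend removal the labelled split gave 2990 calls and the highest of the others 153, for that same crossing split. As many calls as in the labelled split came from 1 of 10 splits, the labelled one itself, and 10 splits are too few for a share under 0.05.

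Genes lower in the libraries labelled Si-CREB3L1 were AT-rich and long. A difference in depth as the cause is argued against, since 2856 calls were made with every library thinned to the smallest total. A trend of reads on GC content and length between libraries is a candidate explanation for much of it. Once it was removed 0 calls were left, although 2600 genes were then at an unadjusted p under 0.05 in edgeR. The 10 named falls then lay at -1.04 to -0.75. They were chosen as the largest falls in these same data, so this does not show that the trend is only part of the cause. With the replicate block added 1171 calls were made (607 shared), but the replicate numbers are shared by title only. Log2 fold change rose with GC content within all 28 tested lists, which the correlation of 0.71 over all genes already fixes, so this decides nothing. The trend varied within the groups as well, since Si-Ctrl replicate 2 deviated by 0.047 for genes under 40% GC where the other Si-Ctrl libraries deviated by 0.47 and 0.44. Whether the trend comes from library preparation or from cells whose AT-rich transcripts truly differ was not tested.

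CREB3L1 was higher in the libraries labelled Si-CREB3L1. Silencing of its RNA by 2-fold or more under the labels as given is argued against: the lower end of the 95% interval was 0.23, and -0.088 with the trends removed. The GC and length trend could account for part of the rise. The median of 106 genes matched on GC content, length and CPM was 0.38, and CREB3L1 was at 0.49 with the trends removed. CREB3L1 lay at percentile 95.3 of the matched genes, within their central 95%. A place within the spread of such low-count genes does not show that the trend accounts for all of the rise. Exchanged labels of the groups stay open. The difference with the trends removed did not pass (log2 0.49, adjusted p = 0.365, and 0.209 to 0.365 over the 4 settings that remove the GC trend). Without removal it passed in 4 other settings. The submitters' codes also bear on an exchange: the letters NC stand in those of the libraries labelled Si-CREB3L1, not in those labelled Si-Ctrl. What the letters stand for is not given, so the codes do not decide it.

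G2/M and mitosis genes were lower in the libraries labelled Si-CREB3L1. The GC and length trend as the whole cause is argued against at the preset correlation, since the list median was -0.20 with the trends removed (camera adjusted p = 7.14e-06), although the adjusted p was 0.674 with an estimated correlation. Fewer cells in G2 and M phase may contribute, but this cannot be told apart here: the 9 members of at least 50% GC had a median of 0.16 (bootstrap 95% interval -0.016 to 0.25) without trend removal and -0.16 (-0.27 to 0.0071) with it. The list also follows the axis that crosses the groups, with 0.24, 0.19 and -0.068 in Si-Ctrl replicates 1, 2 and 3 and 0.12, -0.23 and -0.24 in Si-CREB3L1 replicates 1, 2 and 3, so a link to the label is not shown.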
